A study of Mus musculus with 4 samples.

How the data were processed

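Total RNA of mouse spinal cord at postnatal day 14 had been hybridised to Affymetrix MoGene-1_0-st-v1 arrays, per the file headers, with 2 control and 2 Sip1 cKO arrays that the labels call biological replicates. The animals were of a mixed C57 and 129 background. Groups came from the sample titles and genotypes. The authors' deposited array values are on a log2 scale and were made with RMA, per the submitters' processing notes. RMA corrects background, normalizes the arrays to each other and summarises probes per transcript cluster. Its version, the probe annotation and the genome build were not given in the sources used here. The values were taken as log2 from their range, 1.71 to 14.5, and were not normalized again. Because RMA evens out the arrays, a change shared by most transcripts would not be seen.

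The authors also deposited a table of 420 clusters. Per the file headers it holds clusters between the 10th and 100th percentile of raw expression with a fold change of at least 1.45 between control and mutant, and its fold is the ratio of the higher to the lower group mean. The authors' table gives the group means as linear intensity and as log2 values after a centring that the headers do not describe, and it reports a cluster as up where control was higher. All signs here are Sip1 cKO minus control. No probe annotation of the array was used, so genes were named only through this table: 375 of its clusters carried 1 symbol, 19 several and 26 none. Clusters with several symbols were left unnamed, so a gene listed only among several counts here as not named. Symbols were brought up to date through the gene and accession names of assembly GRCm38.p6, of which no coordinates were used. For 320 clusters the symbol was current, for 40 it was updated through the accession and for 8 through an older symbol, and 7 kept the table's symbol. This gave 369 genes, 6 of them with 2 clusters, where the cluster with the highest mean over the 4 arrays stood for the gene.

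Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, two-sided) on all 35557 clusters with group as the only term, and adjusted p-values are Benjamini-Hochberg values over all clusters. The design had asked for 1 cluster per gene, with clusters tested where names were lacking, so the fit was made over clusters and no filter on signal was applied. With 2 arrays against 2 an exact permutation test of a single value cannot give a two-sided p under 0.333, so genes were judged by the limma fit alone. Values are group mean ± SD with n = 2, and log2 changes carry the standard error of the fit where given. The precision is set by the number of arrays. The procedure was tested on simulated data for the comparison of Sip1 cKO with control, 5 draws over 35557 clusters, where it recovered 7.4% of clusters changed by 1 on the log2 scale and 83.2% of those changed by 2. Of its 486 calls 33 were false and 0 had the wrong sign. So changes near 2-fold often went uncalled in that setting. The simulated noise was independent between clusters, with spreads drawn from a single distribution fitted to all clusters. The rates may therefore differ for the real arrays.

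Gene lists (26, with 549 genes) were fixed from textbook knowledge before the data were examined, as were the groups, the tests, the other settings first listed and the rule for named genes. Only 77 list genes were named, and 5 lists had at least 3 named members. These were tested with limma's camera at a preset correlation of 0.01, against the other named genes only, since other clusters carried no name. Benjamini-Hochberg adjustment ran over the 5 lists. They were also tested with an estimated correlation, with fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes, and against 10000 random lists of named genes matched on level in 5 bins. The share of each list named in the table was compared with the other lists by Fisher's exact test over all 26 lists, a test added after the table was seen. The rule for named genes took Zeb2, the 12 lowest and 12 highest changes past the threshold without clone or model names (or, where fewer passed, the largest at an unadjusted p under 0.05), up to 4 members per list with the smallest p, and a set of genes fixed in advance. Hapln2 and Gpr37 were added after their values were seen. Some genes that the rule takes are not reported here.

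A run of 6613 clusters with the lowest identifiers had no row in the authors' table and varied more between replicates, with a median residual SD of 0.237 against 0.101 for the others. It was kept in the main test and left out in an alternative. Rows with values identical to another row on all arrays numbered 701, and an alternative counted them once. The other alternatives were a second quantile normalization, median centring, a filter on dim clusters, a trend or robust spread in eBayes, the mean of a gene's clusters, array weights, the replicate number as a block, other thresholds and leaving out each array in turn. Genes with no named cluster were left out. Figures were drawn with matplotlib 3.10.9.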

Results

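Gene expression was measured in whole spinal cord of mice at postnatal day 14 on 4 microarrays, each hybridised with total RNA of a separate biological replicate. Sip1, the Smad-interacting protein 1 now named Zeb2, is a zinc finger transcription factor that represses many of its targets. In 2 mutant samples (Sip1 cKO) both copies of the gene were floxed and Olig1-Cre, a recombinase driven from a gene of the oligodendrocyte lineage, was present. The 2 control samples came from littermates with 1 floxed copy and the same Cre. Each array gave a log2 value for 35557 transcript clusters, the units into which this array type groups its probes, and the median value per array lay between 6.62 and 6.70. Pearson's r across clusters was 0.990 between the control arrays, 0.993 between the Sip1 cKO arrays and 0.983 to 0.984 between the groups. Only 2 arrays per group limited the precision of every value.

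The comparison asked how expression across the genome differs in the mutant cord. Zeb2 itself, the targeted gene, fell in Sip1 cKO from a log2 value of 10.38 ± 0.13 to 8.64 ± 0.04 (SD, n = 2 each). This was 3.36-fold lower, a log2 change of -1.75 with a standard error of 0.11 (limma, adjusted p = 0.0144). The control arrays read 10.29 and 10.47 and the Sip1 cKO arrays 8.61 and 8.66, so each array followed its label. Where the probes of this cluster lie relative to the deleted part of Zeb2 was not analysed here. The change ranged from -1.84 to -1.66 when any 1 array was left out, and the adjusted p then ranged from 0.0628 to 0.0888, above the threshold of 0.05. Gemin2, which once shared the symbol Sip1, was not analysed here.

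Of the 12 named genes with the largest decreases past the test, 11 were on the list of myelin and mature oligodendrocyte genes, Mog, Mobp and Mag among them, and 1, Enpp6, was on that of newly formed oligodendrocytes. At an adjusted p under 0.05 (limma, Benjamini-Hochberg over all clusters), 305 clusters were lower and 78 higher in Sip1 cKO, and 270 of the former and 69 of the latter differed by at least 2-fold. The 78 higher clusters held only 29 distinct rows of values, against 305 for the lower ones. Of these 383 calls 50 lay among the 6613 lowest identifiers, which varied more between replicates. Whether those identifiers measure transcripts was not analysed here. Without those identifiers, an alternative chosen after seeing the data, 600 clusters were lower and 218 higher, with a filter on dim clusters 649 and 244, and with an eBayes trend 487 and 116. Gene names came from the authors' deposited table of clusters past a fold cut-off, which named 369 genes. Of these named genes 204 fell, 0 rose and 165 did not pass the test. At an unadjusted p under 0.05, 358 named genes were lower and 4 higher. The authors chose that table on these samples, so the direction of its genes is not independent evidence. The calls depended on the 4 arrays being kept together: 0 clusters passed without control replicate 1 or without control replicate 2, 58 without Sip1 cKO replicate 1 and 60 without Sip1 cKO replicate 2. Fits without control replicate 1 still held 2949 lower and 2611 higher clusters at an unadjusted p under 0.05, those without control replicate 2 held 3527 and 3069, and the complete fit held 3027 and 2826. At that unadjusted threshold higher clusters outnumbered lower ones after median centring (3412 against 2478), after a second quantile normalization (3127 against 2713), with the dim filter (2676 against 1983), with the eBayes trend (3373 against 3010) and without the lowest identifiers (2983 against 2683).

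**Figure D1:**
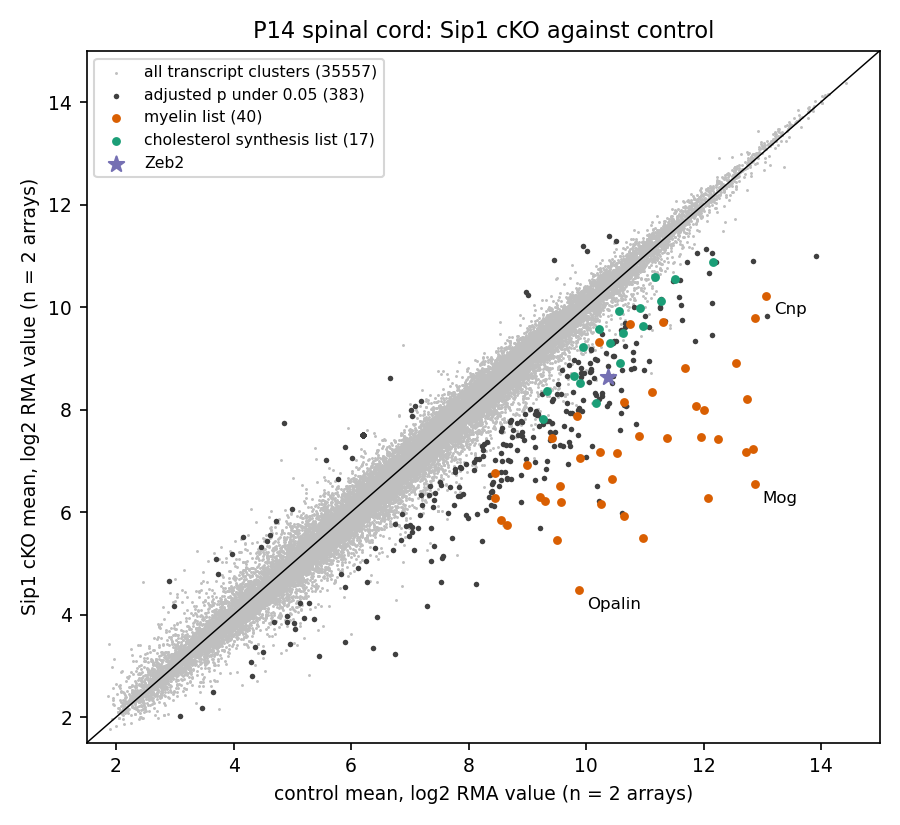
Mean log2 value of each transcript cluster in control (x axis) against Sip1 cKO (y axis), n = 2 arrays per group, with the 383 clusters at an adjusted p under 0.05 in dark grey, the myelin and cholesterol synthesis lists in colour and Zeb2 as a star. Myelin genes such as Mog, at 12.87 in control and 6.55 in Sip1 cKO, lie farthest under the line of equal values.

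Myelin and mature oligodendrocyte genes had the lowest median of the 5 lists tested. Of the 50 genes on this list 40 were named, 38 of them fell, and 2 missed the threshold: Hapln2, a matrix protein of the node of Ranvier, with a log2 change of -2.94 (adjusted p = 0.0563), and Gpr37, an oligodendrocyte receptor, with -1.08 (adjusted p = 0.0517). The median log2 change of the 40 genes was -3.23, against -1.24 for the 292 named genes on no list. Relative to the other named genes the list ranked lower in limma's camera with a preset correlation of 0.01 (adjusted p = 7.87e-13). The call was lost with a correlation estimated from the residuals, with adjusted p = 0.427 with an estimated correlation. Camera compared only genes named through the authors' table, chosen by fold on these arrays, and 364 of the 369 were lower. For every list it therefore gives no rank relative to the unnamed clusters. Adjusted over the list alone, all 40 genes passed, which is not independent evidence since the authors' table was chosen on these samples. Without either control array 0 of the 40 genes passed, and without either Sip1 cKO array 29 did.

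Mog, the myelin oligodendrocyte glycoprotein on the outer face of the sheath, had the largest change of any named gene over the 4 arrays. It fell from 12.87 ± 0.09 to 6.55 ± 1.14 (SD, n = 2 each), a log2 change of -6.32 ± 0.53 (SE) or 79.9-fold (limma, adjusted p = 0.0271). Mobp, a basic protein of compact myelin, fell by 5.80 on the log2 scale. Mag, an adhesion molecule on the inner face of the sheath, fell by 5.61. Cldn11, which forms the tight junctions between myelin layers, fell by 5.55. The Sip1 cKO arrays differed for all 4 genes, with Mog at 5.74 and 7.35 and Cldn11 at 6.37 and 7.99. Without Sip1 cKO replicate 1 the log2 change was -5.52 for Mog, -5.13 for Mobp, -4.92 for Mag and -4.74 for Cldn11, so that Ermn, at -5.68, exceeded Mog. Without Sip1 cKO replicate 2 it was -7.12 for Mog, -6.47 for Mobp, -6.30 for Mag and -6.36 for Cldn11. Ermn, a cytoskeletal protein of myelinating oligodendrocytes, fell by 5.48 and Opalin, a glycoprotein of mature oligodendrocytes, fell by 5.40. Opalin had the smallest p on the list, from 9.88 ± 0.05 to 4.48 ± 0.05 (adjusted p = 0.00256). Mal, a proteolipid of compact myelin, fell by 4.81 and Klk6, a secreted serine protease, fell by 4.71. Trf, the iron carrier transferrin, fell by 4.54 and Fa2h, which hydroxylates the fatty acids of myelin lipids, fell by 4.50. Adamts4, a protease that cleaves matrix proteoglycans, fell by 4.10 and Tspan2, a tetraspanin of oligodendrocytes, fell by 3.78. Cnp, an enzyme of non-compact myelin, fell from 13.06 ± 0.05 to 10.22 ± 0.16, a log2 change of -2.84 (adjusted p = 0.00691). Mbp, a basic protein of compact myelin, was not analysed here.

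**Figure D2:**
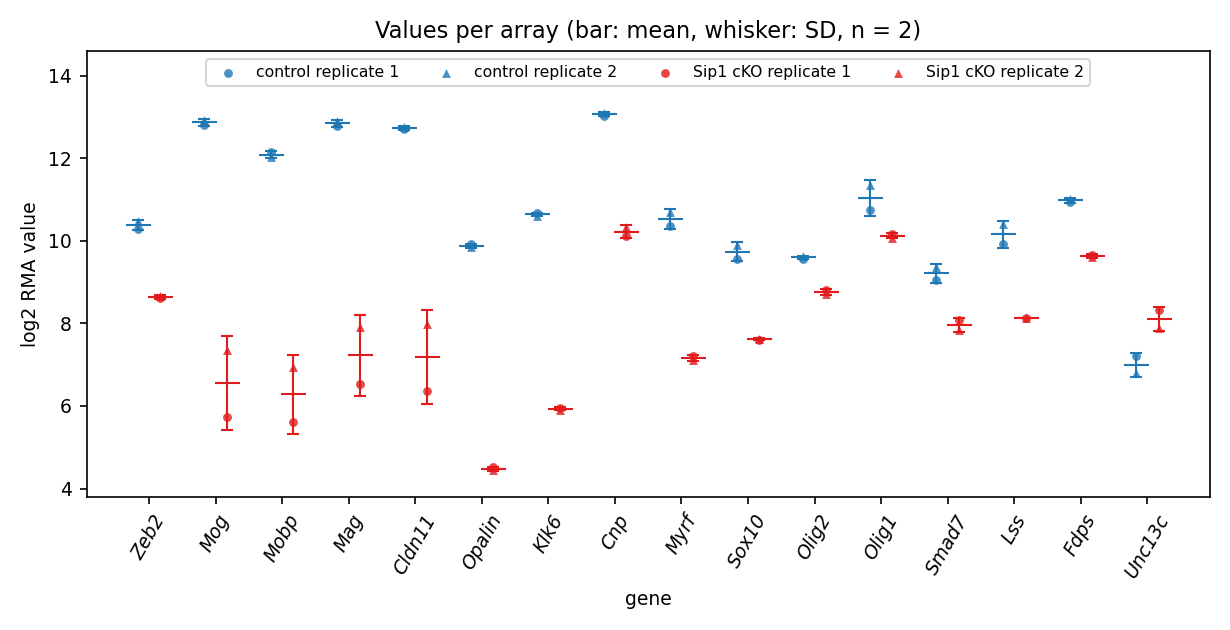
Log2 value (y axis) of named genes (x axis) in each of the 4 arrays, control in blue and Sip1 cKO in red, with circles for replicate 1, triangles for replicate 2, horizontal bars for the mean and whiskers for the SD (n = 2). The Sip1 cKO replicates of Mog, Mobp, Mag and Cldn11 lie apart, while those of Opalin and Klk6 nearly coincide; Olig1, Smad7 and Unc13c did not pass the test.

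Of the 21 genes on the list of newly formed oligodendrocytes only 5 were named, and these 5 fell, with a median log2 change of -2.04. Enpp6, a choline phosphodiesterase that marks oligodendrocytes as they begin to differentiate, fell by 4.64 (adjusted p = 0.00872). Rras2, a small GTPase, fell by 2.33, Cemip2, a hyaluronidase of the cell surface, fell by 1.60, and Lims2, an adaptor of focal adhesions, fell by 1.34. As a group they did not rank apart from the other named genes (camera, adjusted p = 0.339, and 0.953 with an estimated correlation). Adjusted over the list alone, all 5 passed, on the same authors' selection. Without either control array 0 passed, and without either Sip1 cKO array 1 did. None of the 23 genes on the list of oligodendrocyte progenitors, Pdgfra among them, was the single symbol of a cluster in the table. That list was not analysed here.

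Among transcription regulators of the oligodendrocyte lineage, 10 of the 20 on the list were named. Of these 6 fell and 4 did not pass, with a median log2 change of -1.28, and adjusted over the list alone all 10 passed, on the same authors' selection. Myrf, the factor that turns on myelin genes in differentiating oligodendrocytes, fell from 10.53 ± 0.24 to 7.16 ± 0.07, a log2 change of -3.38 (adjusted p = 0.00691). Sox10, a factor present throughout the lineage, fell by 2.12 (adjusted p = 0.0183), Nkx6-2, a homeobox factor of mature oligodendrocytes, fell by 1.70 and Zfp536, a zinc finger protein, fell by 1.26. Olig2, needed to specify the lineage, fell by 0.83, just within the threshold (adjusted p = 0.0497). Its relative Olig1 had a log2 change of -0.92 (adjusted p = 0.179), with control arrays 0.61 apart on the log2 scale. As a group the regulators did not rank apart from the other named genes (camera, adjusted p = 0.915, and 0.953 with an estimated correlation). Nearly all of those genes were lower by the authors' selection, so this does not place the regulators among all clusters. Without either control array 0 passed, and without either Sip1 cKO array 1 did.

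Enzymes of cholesterol synthesis, which supply the main sterol of myelin, were named in 17 of 23 cases and few of them passed the test. All 17 had a negative log2 change between -2.04 and -0.60 and a median of -1.14. Of these 6 fell and 11 did not pass over all clusters, and adjusted over the list alone all 17 passed, on the same authors' selection. Lss, which closes the sterol ring, fell by 2.04 (adjusted p = 0.0280) and Ebp, a sterol isomerase, fell by 1.67 (adjusted p = 0.0305). Fdps, which makes farnesyl diphosphate, fell by 1.34. Although the median was negative, camera placed the list on the higher side of the other named genes, without passing (adjusted p = 0.560, and 0.953 with an estimated correlation). All 17 genes read higher in control replicate 2 than in control replicate 1 (median gap 0.38), as did 239 of the 292 named genes on no list. Leaving out any 1 array left 0 of the 17 genes past the threshold.

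**Figure D3:**
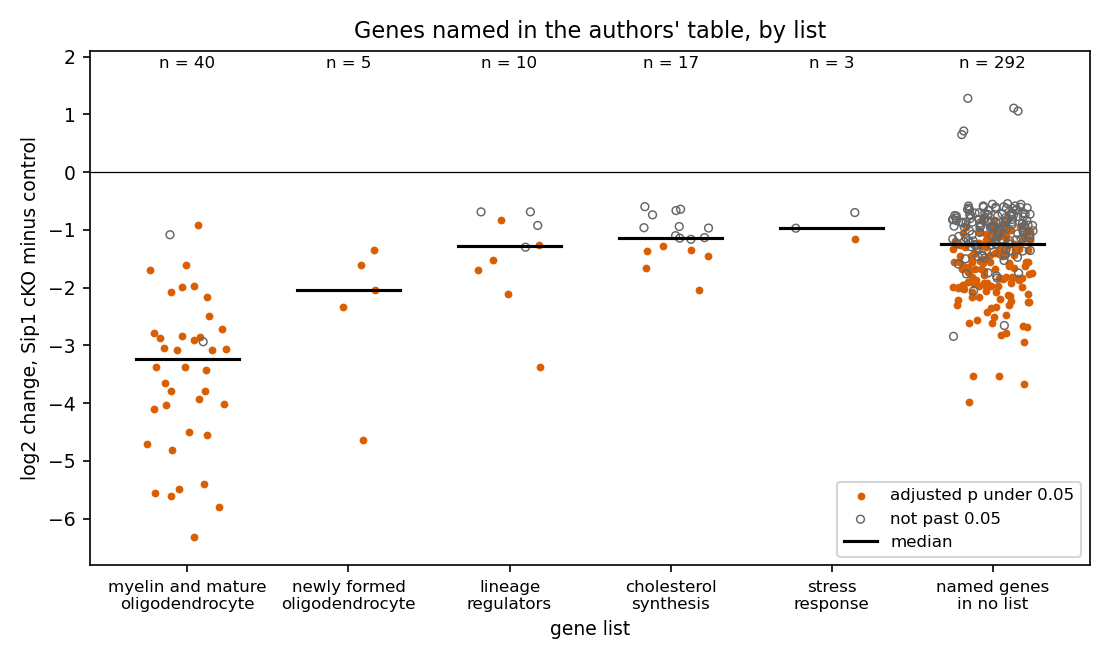
Log2 change (y axis, Sip1 cKO minus control) of the genes named in the authors' table, by gene list (x axis), with filled points for an adjusted p under 0.05, open points for the others and lines for medians. The myelin list has its median at -3.23, and the lineage regulators, cholesterol synthesis genes and genes on no list have theirs at -1.28, -1.14 and -1.24.

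Few genes of signalling and stress pathways were named. Psat1, an enzyme of serine synthesis on the unfolded protein and integrated stress response list, fell by 1.16 (adjusted p = 0.0343). Phgdh, the first enzyme of the same pathway, had a log2 change of -0.70 (adjusted p = 0.119) and Vldlr, a lipoprotein receptor, had -0.97 (adjusted p = 0.0591). These 3 of the 18 genes on the list had a median of -0.97, with camera on the higher side of the other named genes but not passing (adjusted p = 0.688, and 0.953 with an estimated correlation). Smad7, an inhibitor of BMP and TGF-beta signalling and the only named gene of 21 BMP and Smad targets, had a log2 change of -1.25 (adjusted p = 0.0585), from 9.21 ± 0.23 to 7.96 ± 0.17. Nkd1, a feedback inhibitor of the Wnt pathway and the only named gene of 32 on that list, had -0.85 (adjusted p = 0.184). Ptgds, a prostaglandin synthase made by meninges and also by oligodendrocytes, had -0.72 (adjusted p = 0.268). Adjusted over its list alone, all 3 genes of the stress list, Smad7, Nkd1 and Ptgds passed, again on the authors' selection.

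No named gene passed as higher. That was largely set by the naming, since only 5 of the 369 named genes had a positive log2 change. The largest positive changes missed the threshold: Pttg1, the securin that guards sister chromatids, with a log2 change of 1.28 (adjusted p = 0.264), Unc13c, a protein of synaptic vesicle priming, with 1.11 (adjusted p = 0.136), and Cnmd, the cartilage protein chondromodulin, with 1.06 (adjusted p = 0.290). The 78 clusters that rose, 5 of them in the authors' table, carried no single gene name. Of these, 50 held the same values on every array, with a log2 change of 1.30, and the 78 made up 29 distinct rows against 305 for the 305 lower clusters. With identical rows tested once, an alternative chosen after seeing the data, 269 clusters were lower and 24 higher. The 2 largest increases were transcript cluster 10395356, from 4.85 ± 0.12 to 7.73 ± 0.14 (7.35-fold, adjusted p = 0.00691), and transcript cluster 10544017, from 6.66 ± 0.05 to 8.62 ± 0.19 (3.89-fold, adjusted p = 0.0159).

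The lists for other cells and states had no named member and were not analysed here as groups. They covered astrocytes and reactive astrocytes, microglia and phagocytic microglia, neurons and motor neurons, endothelial cells and pericytes, ependymal cells, erythrocytes and skeletal muscle, as well as the cell cycle, interferon response, immediate early genes, Notch genes, sex-linked genes and BMP and TGF-beta ligands, receptors and Smads. Gfap, Id2, Id4, Hes1 and Bmpr1a were therefore not analysed here. The share of a list named in the authors' table was higher than in the other lists for the myelin genes (40 of 50, Fisher's exact test, two-sided, adjusted p = 1.50e-28), the cholesterol synthesis genes (17 of 23, adjusted p = 3.99e-10) and the lineage regulators (10 of 20, adjusted p = 8.36e-04). For each of the other lists the adjusted p was 0.0735 or more. Fisher's test treats genes as independent, but estimated correlations were 0.194, 0.883 and 0.200 within the myelin, cholesterol and regulator lists. The authors' table was also chosen by fold on these same arrays, and 2 genes are on both the myelin and regulator lists. These p-values therefore overstate the certainty.

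The authors' deposited table listed 420 clusters, 398 higher in control and 22 higher in Sip1 cKO. All 420 differed in the same direction in the array values, with r = 0.997 and Spearman's rho = 0.996 for the log2 change across clusters, which are not independent replicates. The authors made the table from these same samples, so a close match was built in. It checks only how the table and its signs were read. Zeb2 was 3.29-fold higher in control in the authors' deposited table. In the limma fit 222 of the listed clusters passed, 217 lower and 5 higher, and 198 did not, while 161 clusters passed that the table as used here did not list.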

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

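The alternatives without the lowest identifiers and with identical rows tested once were chosen after seeing the data. Zeb2 and the myelin list kept their direction in every setting run, and a second quantile normalization, median centring, array weights and the mean of a gene's clusters left the total of 383 calls within 1.5 times (326 to 403). More clusters passed with the filter on dim clusters (893, of which 649 lower and 244 higher), with an eBayes trend (603, of which 487 lower), without the lowest identifiers (818, of which 600 lower and 218 higher), at an adjusted p under 0.1 (712, of which 553 lower and 159 higher) and at an unadjusted p under 0.05 (5853, of which 3027 lower and 2826 higher). At that unadjusted threshold the excess turned to higher clusters with both scalings, the dim filter, either eBayes trend and without the lowest identifiers. With identical rows tested once, 24 clusters were higher, 19 of them at least 2-fold. Leaving out 1 array in turn gave 0 to 60 calls (0 to 59 lower, 0 to 2 higher), all of at least 2-fold, and moved Zeb2 between -1.84 and -1.66 with its call lost each time; the lone array was then assumed to vary like the other group. The replicate numbers share only a number, since same-numbered arrays hardly deviated together (r = 0.0764 across clusters), and with them as a block 111 clusters passed (110 lower, 1 higher), all at least 2-fold, with 1 residual degree of freedom. The myelin list, at a median of -3.23, lost its call with an estimated correlation (adjusted p = 0.427). The lineage regulators lay so close to the other named genes that camera's side turned with median centring (median -1.24), without either Sip1 cKO array (-1.25 without replicate 1, -1.31 without replicate 2), with medians from -1.36 to -1.21 over the arrays left out. Among random lists matched on mean level, the regulators' median of -1.28 lay at percentile 55.9, near the middle. The side of the cholesterol list turned without control replicate 1 (-1.36, with medians from -1.36 to -0.85 over the arrays left out), and none of these passed. In fry, which makes no comparison with other genes, the newly formed oligodendrocyte list (-2.04), the regulators (-1.28), the cholesterol list (-1.14) and the stress list (-0.97) all passed as lower (adjusted p 0.0112 to 0.0204). That outcome was fixed by the selection, since the table names genes by their fold on these arrays and 364 of its 369 genes were lower, so it says nothing about these lists. Apart from the fewer arrays or other clusters in a setting, the cause was not tested. The list tests were not run with a robust spread, which camera does not offer, and testing every cluster as a cluster is the main test itself. Signal over background was not analysed here.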

Other observations

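Beyond the fixed lists, 292 named genes were on none, and the following were chosen after their values were seen from the 12 with the largest decreases, for their known functions. Plxnb3, a plexin receptor for semaphorin 5A, fell by 3.99 on the log2 scale, from 10.21 ± 0.40 to 6.22 ± 0.20 (SD, n = 2 each, limma, adjusted p = 0.0117). Sema4d, a semaphorin made by oligodendrocytes, fell by 2.66 (adjusted p = 0.00599). Cers2, the ceramide synthase for very long acyl chains of myelin lipids, fell from 12.14 ± 0.03 to 9.46 ± 0.05, a log2 change of -2.68 (adjusted p = 0.00569). Tmem63a, a mechanosensitive ion channel, fell by 2.82 (adjusted p = 0.00569), Nipal4, a magnesium transporter, fell by 3.67 (adjusted p = 0.0228) and Cpm, a membrane carboxypeptidase, fell by 3.53 (adjusted p = 0.0140). Pla2g4a, a phospholipase, had a log2 change of -2.84 but missed the threshold (adjusted p = 0.0653), with control arrays that varied by an SD of 0.80. None of these genes passes without either control array, where 0 clusters passed.

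Some named genes differed more within a group than between groups, as values chosen after they were seen. Myoc, which encodes myocilin, read 6.28 and 8.83 in the control arrays and 6.81 and 6.85 in the Sip1 cKO arrays. Named genes of every list tested were mostly higher in control replicate 2 than in control replicate 1: 17 of 17 cholesterol synthesis genes (median gap 0.38 on the log2 scale), 8 of 10 lineage regulators (0.34), 5 of 5 newly formed oligodendrocyte genes (0.27), 3 of 3 stress response genes (0.25), 30 of 40 myelin genes (0.13) and 239 of the 292 genes on no list (0.24). Differences in this gap between the lists were not tested.

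In the 3 patterns that follow, the tests on the excess of lower clusters were chosen after the result was seen. Among the 383 calls at an adjusted p under 0.05, 79.6% were lower in Sip1 cKO. For these calls scaling between arrays is argued against as the whole cause by a share of 76.1%, the lowest over quantile normalization and median centring, and the run of lowest identifiers by a share of 73.3% without it. The excess did not extend to an unadjusted p under 0.05 in these settings, where there were 2478 lower against 3412 higher clusters with median centring, 2713 against 3127 with quantile normalization and 2683 against 2983 without the lowest identifiers. Of the 3 ways to split the 4 arrays into pairs, 1 gave as many calls, the real one, and the highest of the others gave 0, but so few splits cannot give a share under 0.05. Genotype remains a candidate explanation, and so do differences between these few animals and a loss of cells in place of lower expression per cell. The higher Sip1 cKO value of Zeb2 lay below the lower control value by a log2 difference of -1.63. This checks the labels and cannot decide what caused the excess of lower clusters.

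The named myelin genes had a lower median log2 change than lineage regulators and the other named genes, a difference from the latter that camera did not call with an estimated correlation (adjusted p = 0.427). Signal level in control is argued against as the cause, since the median of -3.23 lay at percentile 0 of 10000 random lists of named genes matched on that level. An equal loss of all cells of the lineage, with both lists expressed there alone, would give like medians if background did not limit the drops. The medians were -3.23 for 38 myelin genes and -1.09 for 8 regulators, after leaving out 2 genes on both lists (two-sided permutation p = 0.00128, 100000 resamples across genes, which are not independent). Signal over background was not analysed, and only genes past the fold cut-off of the authors' table were compared. The medians therefore differed among these named genes, but the p-value cannot decide on an equal loss of cells. A block at differentiation, with progenitors kept, may give this order, but regulator RNA from progenitors or other cord cells was not measured, so it stays open.

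The authors' table was more one-sided than the array values at the same fold, with 398 of its 420 clusters lower in Sip1 cKO (94.8%) against 497 of 944 clusters past the fold that it did not list, outside the lowest identifiers (52.6%). Low signal is argued against as the cause, since unlisted clusters brighter than the median listed one were lower in 63.2% of cases (95% exact interval 56.0 to 70.0). A filter on the spread between replicates, at an unadjusted p under 0.05 in limma, left 53.5% lower among unlisted clusters (50.1 to 56.8). It kept 868 of the 944, so the share could hardly move. A stricter filter on spread was not tested and stays open. With identical rows counted once the share was 55.2% (51.8 to 58.5). A further selection step in making the table, or rows of it not used here, may account for the difference, and no biological explanation was tested.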
